A study of Caenorhabditis elegans with 2 samples.

How the data were processed

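ChIP-seq peak lists of CHD-7 fused to GFP and FLAG were analysed for 2 biological replicates of transgenic C. elegans strain OP609, collected as mixed-sex young adults 67 hours after synchronisation. Per the labels, chromatin was sheared by sonication and precipitated with an antibody against GFP. The submitters' deposited notes state that each list was called against 1 control alignment, that each replicate and the pool of both gave a list of peaks and background, and that the reproducible list was derived from the replicate and pooled lists by the irreproducible discovery rate (IDR). The peak caller, the aligner, their versions and the IDR cutoff are not given in the sources used here. The control experiment was not analysed here. Samples were grouped by their descriptions into a single group, which leaves no comparison between conditions and no paired fit.

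The authors deposited each list in the narrowPeak layout on the ce10 and ce11 builds. The deposited signal column holds the peak caller's value per peak, and it was used only to rank peaks within a list. The deposited −log10 q column was tied at its highest value of 3.43 for 1350 of the 1884 reproducible peaks and was not used for ranking. The p column holds a constant and was not used. Replicate and pooled lists held 30000 entries each, and the reproducible list 1884 on ce11 and 1934 on ce10. Signal ranged from 31.7 to 3774 in replicate 1, from 23.8 to 1495 in replicate 2 and from 166 to 5232 in the reproducible list. In 11 cases the reproducible list repeats an interval with another summit, and these entries were kept. The files hold no read counts, so the depth per sample is unknown, and the intervals given cover counts of peaks and genes, not read depth.

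Positions on ce11 were set against the WBcel235 assembly, which is the same sequence, and its Ensembl gene annotation. The ce10 lists served only where no annotation was needed, and no coordinate was converted between builds. A summit is the start plus the deposited offset. A promoter window ran from 1000 bp upstream to 200 bp downstream of the annotated 5′ end of a gene, and a gene class is the annotated biotype. Each summit was given 1 position in the order coding exon, 5′ UTR, 3′ UTR, non-coding exon within a protein-coding gene, intron, other non-coding exon, intergenic.

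Overlap of the replicates was taken between equal numbers of top-ranked peaks, since the whole lists hold background. Overlap, promoter share and positions were tested by moving all summits of a chromosome together by a random offset, 1000 times, so that the spacing of peaks was kept, and the smallest p is 0.000999 one-sided. Gene lists and biotypes were tested by two-sided Fisher's exact tests among genes with at least 1 pooled candidate summit in the window, with Benjamini-Hochberg adjustment over 26 lists and 10 biotypes of at least 20 such genes. A list needed 5 members in this background. X and the middle one of 3 equal parts of each autosome were tested by Fisher's exact test against pooled candidates that overlap no reproducible peak, with intervals from 2000 bootstrap draws of 500 kb blocks. Presence of 2080 6-mers within 75 bp of the summit was compared with a window 1000 bp away by the exact McNemar test, at an adjusted p of 0.05 and a ratio of 1.5. Shares of peaks have 95% Wilson intervals. The odds ratios assume independent genes, although neighbouring genes can share a window: 2324 of the 6148 background genes had a window overlapping another one.

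The 26 gene lists, the tests and the named-genes rule were fixed before the data were examined, and 3 list symbols had no match in the annotation. The rule named the genes whose windows held the 15 highest promoter summits, with both genes of a shared window, and the 3 members of highest signal of each list that passed (fewer where fewer had a summit). It also named chd-7, unc-119, dbl-1, daf-7, sma-9, lon-2, daf-16 and bar-1 always, and the 2 members of highest signal of the 3 biotypes of lowest p. Other genes named were chosen after their values were seen.

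Alternatives fixed beforehand were the peaks of a single replicate, the higher-ranked 942 peaks, the 1884 top-ranked pooled candidates, windows of 500 bp up and 100 bp down or 2000 bp up and 500 bp down, whole intervals in place of summits, all genes as background, shared windows left out, chromosome lengths as background, the ce10 lists, the middle 50% of chromosomes, other overlap rules and list lengths, 6-mer windows of 50 and 100 bp or the opposite flank, and regions of 30 and 100 kb around chd-7 and unc-119. Added later were GC bins of 2% (a Cochran-Mantel-Haenszel test, or 1 candidate drawn per peak from its bin for 6-mers), leaving out summits within 100 bp of tRNA, snoRNA, snRNA or rRNA genes, counting summits within 100 bp of the gene body, leaving chd-7 out of the gene lists, and counting overlapping intervals around chd-7 and unc-119 once.

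The functions were tested on simulated data first. Of 96 simulated gene lists with summits at 40% of their genes against 13% elsewhere, 47.9% were called overall and 100% of those with at least 50 members, and 0.249% of other lists were called (19973 genes). Simulated genes received summits independently, whereas neighbouring genes in the data can share one, so the 0.249% need not hold for the data. Uniform peak sets passed the promoter test in 1% of 100 cases, and all 20 enriched sets passed. Of 20 6-mers planted in 15% of windows, 17 passed, and the others were already in at least 25.5% of flanks, too common to reach the ratio. A planted share of 50% gave a replicate overlap of 50.5%, and a planted X odds ratio of 1.5 gave a mean of 1.48. Computation used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9, with fixed seeds.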

Results

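CHD-7 is the worm counterpart of vertebrate CHD7, a chromatin-remodelling ATPase of the chromodomain helicase family whose gene is mutated in CHARGE syndrome. Its positions on the genome were measured in whole Caenorhabditis elegans by chromatin immunoprecipitation and sequencing (ChIP-seq). Worms of strain OP609 carried an integrated transgene that makes CHD-7 fused at its C-terminal end to GFP and FLAG, and the fusion was precipitated with an antibody against GFP. Mixed-sex young adults were collected 67 hours after synchronisation from starved first-stage larvae. There was 1 group of 2 biological replicates and no second condition, so the comparisons below set peaks against background regions, gene classes and shifted positions. The files held peaks and no read counts, so the depth of the libraries is unknown. The reproducible list, called by the authors from both replicates, held 1884 peaks on the ce11 build, with a median width of 390 bp. They were the same peaks as the 1884 pooled entries of highest signal, so a single member need not rank high in both replicates. Positions are those of ce11, and the signal of a peak is the authors' value, used only to rank peaks within a list.

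Both replicates placed their strongest peaks at largely shared sites. Of the 1884 top-ranked peaks of replicate 1, 1106 overlapped a peak of replicate 2's top 1884 by at least 1 bp, or 58.7% (95% Wilson interval 56.5% to 60.9%). Shifting the peaks around each chromosome gave 1.39% on average and 2.49% at most, so the share was above all 1000 shifts (one-sided permutation p = 0.000999, the smallest the shifts can give). Sharing was higher among stronger peaks, at 76% of the 50 top-ranked and 63.7% of the 1000 top-ranked. Of the reproducible peaks, 1837 were met by an entry of replicate 1's 30000-entry list and 1878 by one of replicate 2's. Within the 1884 top-ranked entries these shares were 77.2% and 77.1%. The peaks at rpl-3, tasp-1, hsp-60 and cox-5A ranked within the 50 highest in both replicates, whereas the peak upstream of daf-16 ranked 6555 in replicate 1 and 751 in replicate 2. All Wilson intervals cover counting error only.

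**Figure D1:**
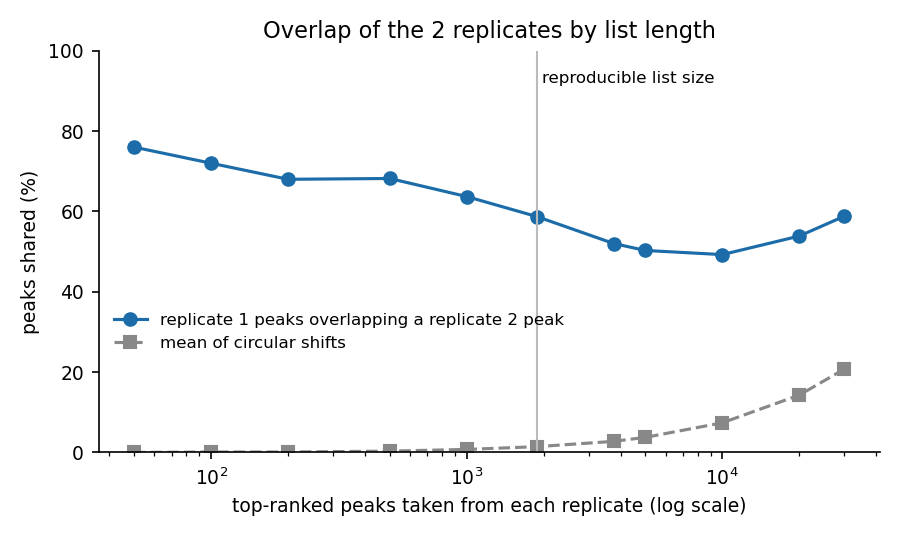
Share of replicate 1 peaks (%) that overlapped a replicate 2 peak by at least 1 bp, against the number of top-ranked peaks taken from each replicate (log scale), with circles for the data and squares for the mean of circular shifts. The share fell from 76% at 50 peaks to 58.7% at the size of the reproducible list. There the shifts drawn for this figure, a separate set from those in the text, gave about 1.44%.

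CHD-7 summits lay in intergenic sequence and in non-coding exons more often, and in introns and coding exons less often, than shifted positions did. Intergenic sequence held 833 summits, 44.2% (95% Wilson interval 42% to 46.5%) against 34.5% after shifting. Exons of non-coding RNA genes held 118 summits inside protein-coding genes, 6.26% against 0.758%, and 188 elsewhere, 9.98% against 2.64%. Exons of tRNA, snoRNA and snRNA genes belong to this class, so these summits can be the same as those counted at such genes below. The 5′ UTR share of 2.87% was also above the shifted 1.42%. Fewer summits than after shifting lay in introns, at 20.2% against 32.8%, and in coding exons, at 13.3% against 24.5%. Each of these differences had a two-sided permutation p of 0.002, the smallest the shifts can give, whereas the 3′ UTR share of 3.13% did not differ from the shifted 3.35% (p = 0.687). The authors' other pooled candidates, which did not reach the reproducible list, lay in coding exons in 42.7% of cases. The replicates differed here. Coding exons held 21.8% of replicate 1's top-ranked summits and 9.18% of replicate 2's (odds ratio 2.75). Intergenic sequence held 38.1% and 49.8% (odds ratio 0.62). With 1 library each, a test over peaks cannot stand for replicates, so its p is not given. Replicate 1's coding share lay just under the central 95% of shifts of the reproducible list, 22.4% to 26.9%, and replicate 2's lay farther below. Shifts of each replicate's own peaks were not run. Both shares were below the 42.7% of other candidates, so the deficit in coding exons was present in both replicates and larger in replicate 2.

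**Figure D2:**
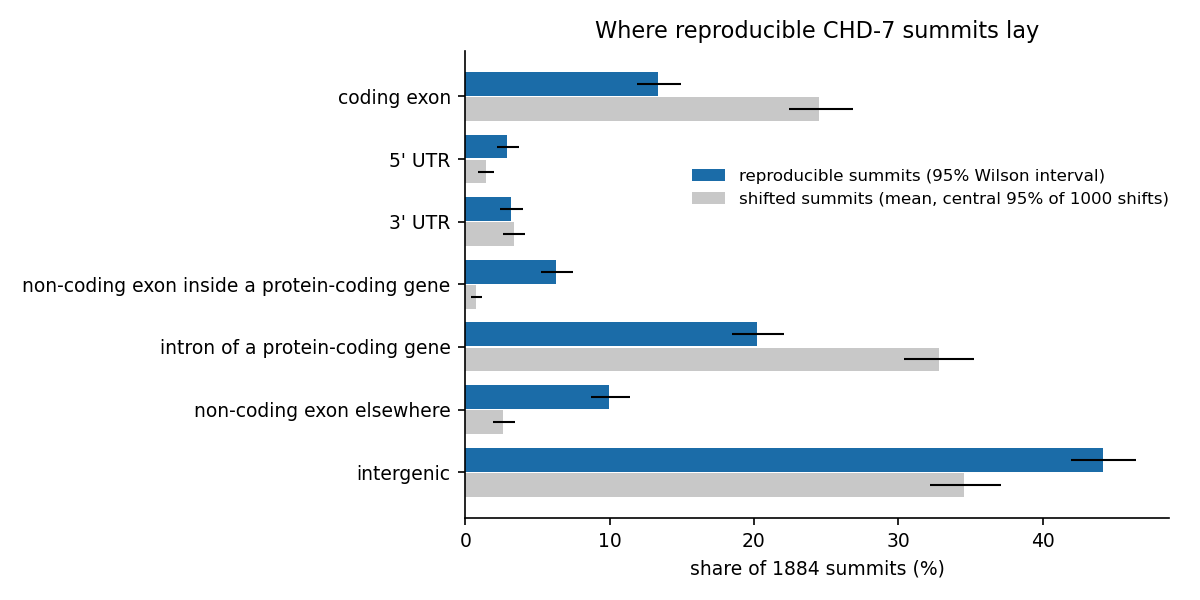
Share of the 1884 reproducible summits (%) in each kind of annotated sequence, as blue bars with 95% Wilson intervals, beside the mean of 1000 circular shifts as grey bars with the central 95% of the shifts. Intergenic sequence and non-coding exons held more summits than the shifts gave, and introns and coding exons held fewer, at 20.2% and 13.3%.

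Promoters of protein-coding genes held more summits than shifted positions did. From 1000 bp upstream to 200 bp downstream of an annotated 5′ end lay 706 summits, 37.5% of the list (95% Wilson interval 35.3% to 39.7%), a 1.77-fold excess over the shifted mean of 21.2%. No shift gave more than 25% (one-sided permutation p = 0.000999, the smallest possible). Other candidates lay there in 21.6% of cases, and candidates of matched GC content in 20.6%. In all, 834 of 19973 protein-coding genes had a reproducible summit in this window, or 13.6% of the 6148 genes with any candidate summit. Stronger peaks were at promoters more often: 198 of the 471 summits of highest signal, 42%, against 151 of the 471 of lowest signal, 32.1% (two-sided Fisher's exact test, p = 0.00189). That difference of 9.98 percentage points shrank to 3.83 among the higher-ranked 942 peaks alone (Fisher's exact p = 0.455), and to 6.37 when whole peak intervals were counted (p = 0.0552).

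The promoter peak of highest signal lay 284 bp upstream of rpl-3, a protein of the large ribosomal subunit (chromosome III, 3867404 to 3867732, signal 1457, rank 2 in both replicates). It was followed by the peak at tasp-1, a taspase-like protease, at III 10759102 to 10759458 (signal 1321), in a window shared with K01G5.10. Next came the peak between nhl-2, an RNA-binding cofactor of microRNA silencing, and tag-340 (III 4899738 to 4900095, signal 1087), whose summit was inside a non-coding RNA exon. The peaks assigned to H41C03.3 (II 5844633 to 5845028, signal 1019) and to egg-5, which acts in egg activation (I 4172008 to 4172564, signal 989), lay at the spliced-leader genes sls-2.1 and sls-2.4. The divergent HSP70-family genes F44E5.4 and F44E5.5 shared a peak at II 11759307 to 11759637 (signal 962). Further down were epn-1, an epsin (signal 903), rpl-20 with its neighbour Y17G9B.5 (888), cdc-48.1, a p97-type ATPase (884), and cbp-1, a histone acetyltransferase of the CBP and p300 family (841). The last of the 15 highest were cls-2 and R107.5 (805), serp-1.1 (800), rpl-35 (787), rpl-15 and K11H12.8 (787), and nspc-17 (775). With the narrower window of 500 bp upstream and 100 bp downstream, the summits at K01G5.10, nhl-2, tag-340, H41C03.3, egg-5, cbp-1, cls-2 and nspc-17 fell outside.

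Ribosomal protein, stress response, vacuolar proton pump and oxidative phosphorylation genes carried promoter peaks more often than other genes with a candidate summit. Whether open chromatin at highly transcribed genes gave such peaks was not tested, since neither the control nor expression was analysed here. Of 56 cytosolic ribosomal protein genes, 20 had one, 35.7% against 13.4% of other genes (odds ratio 3.6, 95% exact interval 1.96 to 6.43, adjusted exact p = 5.8e-04). Among them were rpl-3, rpl-20, rpl-35, rpl-15 and rps-1. Stress response genes had a summit in 7 of 16 cases (odds ratio 4.99, 1.57 to 15.1, adjusted exact p = 0.0268). They included the mitochondrial chaperonin hsp-60 (III 1618998 to 1619255, signal 721), the constitutive HSP70 hsp-1 (IV 17278347 to 17278706, 605) and the endoplasmic reticulum chaperone hsp-3 (X 6092072 to 6092278, 589). The small heat shock genes hsp-16.2 and hsp-16.41 shared 1 summit, so the 7 genes rested on 6 peaks. The stress response call held in 7 of 10 alternative settings (adjusted p from 6.2e-04 to 0.374). Of 10 genes for the vacuolar proton pump, 5 had a summit (odds ratio 6.40, 1.47 to 27.9, adjusted exact p = 0.0334), led by vha-12 (X 4190560 to 4190949, signal 285), vha-2 (III 9782025 to 9782414, 236) and vha-20 (X 14164242 to 14164631, 228). That call held in 4 of the 10 alternative settings (adjusted p from 0.00499 to 0.154). Of 16 oxidative phosphorylation genes, 6 had one (odds ratio 3.84, 1.14 to 11.7, adjusted exact p = 0.0475), led by the cytochrome oxidase subunits cox-5A (III 12905076 to 12905298, signal 711), cox-5B (I 9788602 to 9788791, 566) and cox-6A (III 5080884 to 5081007, 370). The peak assigned to cox-6A lay 797 bp upstream of it, within 100 bp of the snRNA gene F54D8.7. The oxidative phosphorylation call held in 1 of the 10, and without summits at small RNA genes, chosen after the data were seen, it did not pass (adjusted exact p = 0.0875, with 0.00581 to 0.511 over the alternatives).

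Chromatin regulators had promoter peaks in 8 of 23 genes (odds ratio 3.42, 95% exact interval 1.25 to 8.63, adjusted exact p = 0.0359). The strongest lay at swsn-7, a SWI/SNF subunit (II 8028217 to 8028606, signal 435), at chd-7 itself (I 4699396 to 4699514, 385) and at lin-53, a histone-binding RbAp48-type protein (I 9619914 to 9620054, 312). The others were jmjd-1.2, lin-35, met-1, chd-1 and set-2, with signals from 263 to 180. The list was fixed with chd-7 in it, the gene the transgene carries. With chd-7 left out, an alternative chosen after the data were seen, 7 of 22 had a summit and the list did not pass (odds ratio 2.99, adjusted exact p = 0.0717, with 6.2e-04 to 0.374 over the alternatives).

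Chemoreceptor genes, F-box and MATH-domain genes and innate immunity effectors carried promoter peaks less often, the last 2 groups in 4 and 5 of 10 alternative settings (adjusted p from 1.5e-04 to 0.626 and from 0.00282 to 0.432). Chemoreceptor genes had a summit in 7 of 163 cases, 4.29% against 13.8% of other genes (odds ratio 0.280, 0.110 to 0.593, adjusted exact p = 0.00146). The highest of these, upstream of sre-23 (I 8259455 to 8259663, signal 529), lay at the snoRNA gene ZK265.10. The next, upstream of srh-269 (V 16592204 to 16592559, signal 468), lay at a tRNA gene, and that of srh-70 (II 12518829 to 12519218, 293) at the snoRNA gene T21B4.20. F-box and MATH-domain genes had 2 of 66 (odds ratio 0.197, 0.0233 to 0.745, adjusted exact p = 0.0334), fbxb-72 (V 723910 to 724102, signal 298) and fbxa-202 (V 6326342 to 6326731, 188). Innate immunity effectors had 4 of 87 (odds ratio 0.304, 0.0807 to 0.811, adjusted exact p = 0.0400), led by ilys-5 (X 6536707 to 6537096, signal 246), spp-26 (V 6559568 to 6559957, 245) and clec-126 (II 3518992 to 3519381, 238). The summits at spp-26 and clec-126 lay within 100 bp of tRNA genes. Of 1365 annotated chemoreceptor genes only 163 had any candidate summit and entered this test.

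The other 18 of the 26 lists did not pass, by Fisher's exact test with Benjamini-Hochberg adjustment. Translation factors came nearest, with 6 of 19 genes and an adjusted p of 0.10, among them the elongation factor genes eef-2 and eef-1A.1. Cuticle collagens had 2 of 50 (adjusted exact p = 0.151) and neuropeptides 1 of 32 (0.273). Counts were 2 of 6 heterochronic genes, 3 of 13 in Wnt pathways, 2 of 10 in insulin and dauer hormone signalling, and 2 of 11 in TGF-beta pathways (kin-29 and sma-2). The peak at sma-2 met no entry of replicate 1's list and ranked 2175 in replicate 2. The remaining lists follow. Summits were at 13 of 81 nuclear hormone receptors, 4 of 27 histones, 5 of 38 mitochondrial ribosomal proteins and 2 of 20 proteasome genes. Tissue lists gave 2 of 13 for intestine, 2 of 14 for muscle, 1 of 12 for neurons, 1 of 16 for germline, 1 of 24 for sperm, and 2 of 29 each for epidermis and molting and for Hox and homeobox genes. Of 10 alternative settings, the ribosomal call held in all but the one without shared windows (adjusted p from 1.1e-09 to 0.128), and the chemoreceptor call in all but the narrower window (2.9e-16 to 0.170). The chromatin regulator call held in 5. Among the 10 settings was leaving chd-7 out, which hardly moved the odds ratios of the other lists (6.41 against 6.40 for the vacuolar proton pump). For those lists it is a weak check. With the peaks of a single replicate, 3 or 4 lists passed in place of 8, and 1 list passed with the narrower window or without shared windows.

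**Figure D3:**
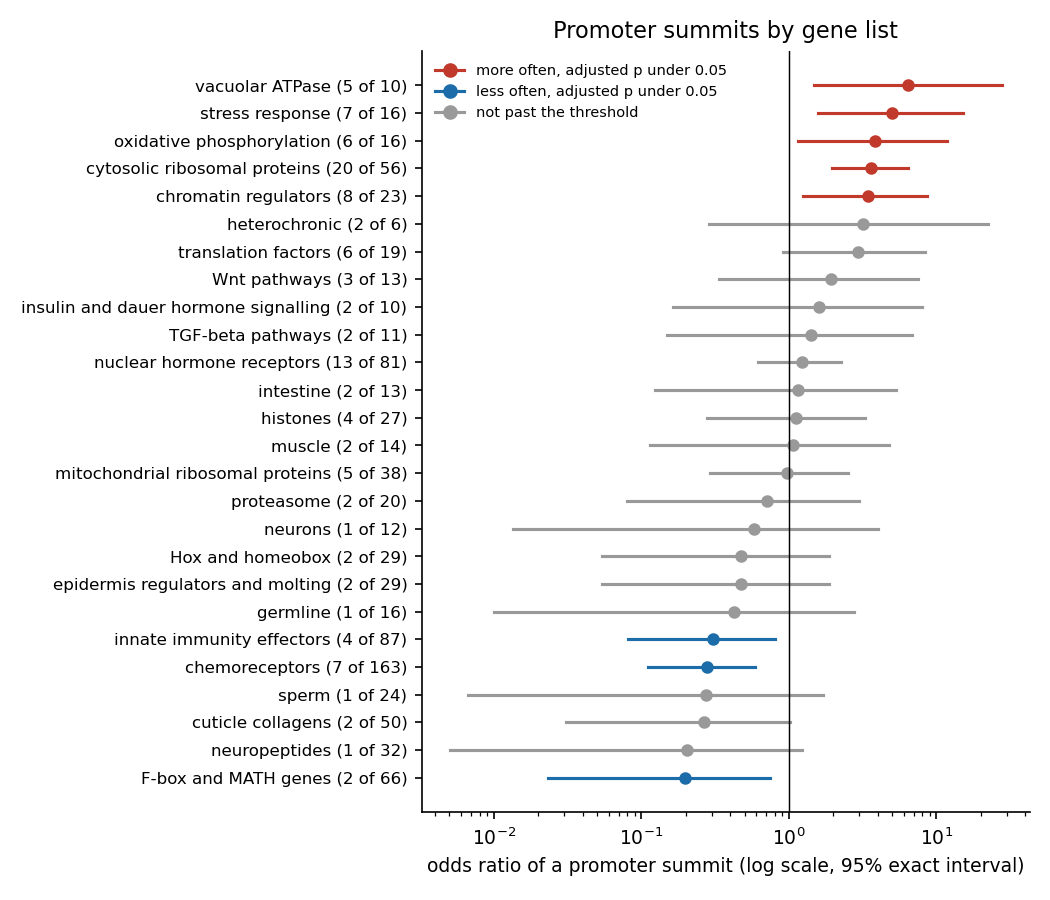
Odds ratio (log scale) of a reproducible summit in the promoter window for each of 26 gene lists, with 95% exact intervals and the count of genes with a summit among those with a candidate summit. Red lists were above and blue lists below an odds ratio of 1 at an adjusted p under 0.05, from 6.40 for the vacuolar proton pump to 0.197 for F-box and MATH genes.

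Among 10 annotated gene classes, tRNA, snoRNA and snRNA genes had the highest shares with a reproducible summit. In the same window, 262 of 458 tRNA genes with a candidate summit had a reproducible one, 57.2% against 14.8% of other genes (odds ratio 7.71, 95% exact interval 6.34 to 9.40, adjusted exact p = 6.1e-91). For snoRNA genes, which guide modification of ribosomal RNA, the count was 95 of 225 (odds ratio 3.85, adjusted exact p = 1.2e-19), and for snRNA genes 21 of 59 (2.82, adjusted exact p = 5.1e-04). The snRNA class includes spliced-leader genes such as sls-2.1 and sls-2.4. Protein-coding genes as a class had one in 834 of 6148 (odds ratio 0.632), pseudogenes in 16 of 362 (0.228) and piRNA genes in 66 of 616 (0.594), with adjusted p of 4.7e-19, 2.7e-12 and 8.6e-05. The miRNA (23 of 109), lincRNA (12 of 54), antisense RNA (3 of 35) and ncRNA (542 of 3305) classes did not pass. Measured against all annotated genes, the direction turned for protein-coding genes (odds ratio 1.08, adjusted exact p = 0.124, with 3.1e-87 to 0.124 over the alternatives) and ncRNA genes (2.13), and the piRNA call ended under 4 of 9 alternatives. The snRNA call ended without shared windows (adjusted exact p = 0.0953, with 8.3e-08 to 0.0953 over the alternatives).

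Summits were also counted by their distance to the genes themselves. Within 100 bp of a tRNA gene were 219 summits, 11.6% of the list (95% Wilson interval 10.3% to 13.2%), against 3.37 after shifting, a 65.1-fold excess. The same count was 70 for snoRNA genes (32.0-fold) and 23 for snRNA genes (33.8-fold). It was 355 for ncRNA genes, 18.8% of the list (7.84-fold), and 160 of these also lay within 100 bp of a tRNA, snoRNA, snRNA or rRNA gene. None lay at rRNA genes, where shifts gave only 0.219, and 4 at piRNA genes, where shifts gave 34.7. The tRNA share was 10.2% in replicate 1's top-ranked peaks and 10.8% in replicate 2's, against 0.567% of the other candidates. In all, 229 of 612 annotated tRNA genes and 70 of 346 snoRNA genes had such a summit (one-sided permutation p = 0.000999 for tRNA, snoRNA, snRNA and ncRNA classes, the smallest possible). The strongest snoRNA peaks were at ZK994.7, inside pxn-1 (V 8500408 to 8500706, signal 1105), and at C51F7.3, inside frm-7 (V 12303473 to 12303798, 970). The peak at ZK994.7 also lay 934 bp upstream of the tRNA gene WBGene00023221, the tRNA gene whose window held the highest signal. Next among tRNA genes was WBGene00000308 (X 13665474 to 13665713, signal 605). The measure by gene body was chosen after the data were seen.

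**Figure D4:**
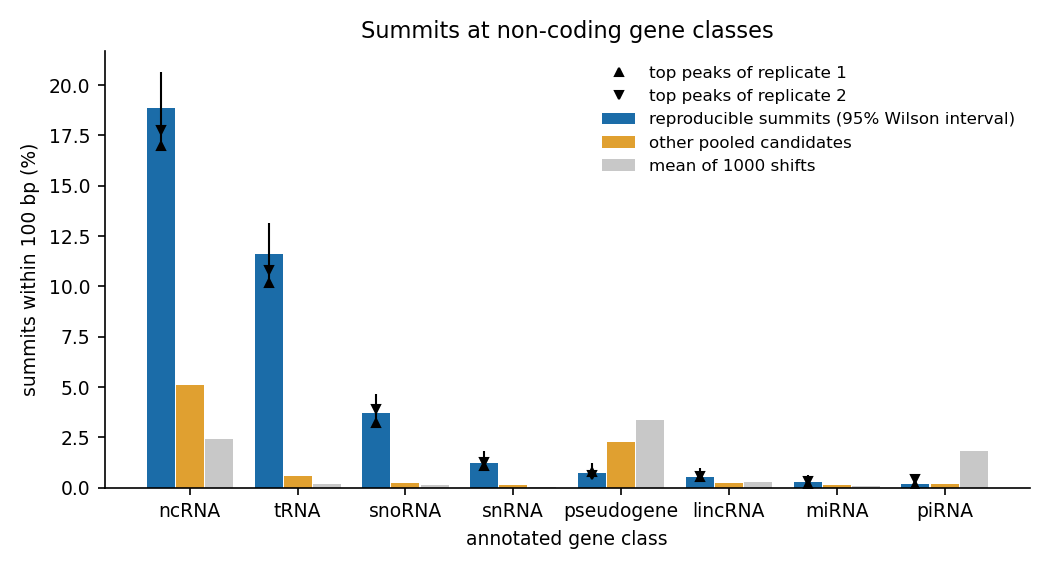
Share of summits (%) within 100 bp of a gene of each annotated class, for reproducible peaks (blue, 95% Wilson intervals), other pooled candidates (orange) and the mean of 1000 shifts (grey), with triangles for the top-ranked peaks of each replicate. The tRNA class held 11.6% of reproducible summits and 0.567% of other candidates.

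The X chromosome held 22.97 peaks per megabase against 17.89 over the autosomes together, and chromosome III held 23.07. Of reproducible peaks 407 of 1884 were on X, 21.6% against 18.2% of other candidates (odds ratio 1.24, 95% block-bootstrap interval 1.07 to 1.43, two-sided Fisher's exact test p = 3.3e-04). X also carried 276 of the 612 tRNA genes, and 36.3% of the summits at small RNA genes against 18.7% of the others. Without summits within 100 bp of tRNA, snoRNA, snRNA or rRNA genes in either list, an alternative chosen after the data were seen, the odds ratio was 1.04 (Fisher's exact p = 0.591, with p from 1.3e-05 to 0.591 over the alternatives). Chromosome V held fewer peaks than its candidates implied (299, odds ratio 0.779, adjusted exact p = 5.2e-04), and chromosomes I to IV did not differ (adjusted p from 0.215 to 0.582). On autosomes, 637 of 1477 peaks, 43.1%, lay in the middle of the 3 equal parts of the chromosome, where genes are denser, against 34.6% of candidates (odds ratio 1.43, 1.22 to 1.68, Fisher's exact p = 6.1e-11).

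The sequence at summits was rich in G and C and in repeats of GA. GC content averaged 47.2% (SD 7.32) in the 151 bases around 1884 summits, 37.0% (SD 7.73) in windows 1000 bp away, and 43.5% at other candidates, with 35.4% in the genome. Of all 6-mers, each counted with its reverse complement, 588 were present at summits at least 1.5 times as often as in the flanks, and 333 were lower by that factor, at an adjusted p under 0.05 (two-sided exact McNemar test). The largest ratios belonged to CCCGGG (3.87% of summits against 0.478% of flanks), ACGCGG (7.75% against 1.22%) and CACGCG (10.1% against 1.91%). GAGAGA was present at 30.3% of summits and 9.98% of flanks (adjusted exact p = 1.2e-51). Against candidates drawn to the same GC content, chosen after the data were seen, 179 6-mers passed, 148 of them among the 588. GAGAGA was still at 30.3% against 13.2% there (adjusted exact p = 4.5e-33). The ratios of CCCGGG, ACGCGG and CACGCG dropped to 2.43, 1.72 and 2.65 in that comparison, from 8.11, 6.35 and 5.31 against flanks. With small RNA gene summits left out as well, CCCGGG (2.29% against 2.03%) and ACGCGG (5.66% against 4.07%) did not pass (adjusted exact p = 0.855 and 0.139), while CACGCG did (9.22% against 4.45%). Overlapping 6-mers share bases, so these counts are not counts of separate motifs.

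The region of chd-7 itself held more reproducible peaks than most places on its chromosome. The 50 kb around the gene (I 4685865 to 4698575, minus strand) held 5, against 0.932 after shifting (one-sided permutation p = 0.0330). The strongest was at 4701287 to 4701482 (signal 701, rank 47 in replicate 1 and 39 in replicate 2), upstream of the gene and in a non-coding exon. Another lay 877 bp upstream of the 5′ end (signal 385), while a weaker interval overlapped the strongest peak (4701395 to 4701784, signal 189), and both met the same entry in each replicate's list. With overlapping intervals counted once, an alternative chosen after the data were seen, the region held 4 places against 0.893 after shifting (permutation p = 0.0470). The other 2 lay in coding exons of chd-7, at 4696727 to 4697116 (246) and 4697593 to 4697982 (187). The latter ranked 775 in replicate 1 and 29808 in replicate 2. Replicate 1's top-ranked peaks gave 9 summits in this region (permutation p = 0.00699) and replicate 2's gave 2 (p = 0.243), with p from 0.00699 to 0.243 over the alternatives. No reproducible peak lay in the 50 kb around unc-119 (III 10902641 to 10908935), where shifts gave 1.17. That gene is mutated in the strain, and the transgene carries an unc-119 rescue beside the tagged chd-7.

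**Figure D5:**
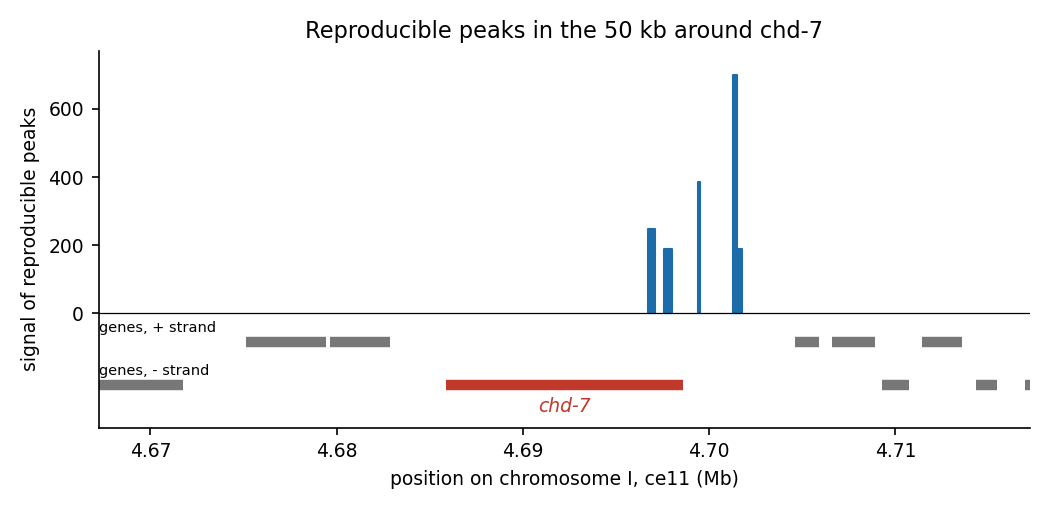
Reproducible peaks in the 50 kb around chd-7 on chromosome I (position in Mb, ce11), drawn from start to end with the authors' signal as height, above protein-coding genes on each strand. The 5 peaks lie at the 5′ end of chd-7, which is on the minus strand, and upstream of it, with signals from 187 to 701.

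The forkhead factor gene daf-16 had 1 summit in its promoter window (I 10749912 to 10750301, signal 199) and 6 more inside the gene, the strongest in an intron (10769737 to 10770126, signal 330). Among TGF-beta pathway genes, dbl-1, a BMP-like ligand, had none in its window and 1 in a coding exon at V 6758199 to 6758588 (signal 198), which the wider window and the interval count took in. The cofactor gene sma-9 had none in its window, 2 in its introns (signals 239 and 289) and 1 farther upstream at X 10766295 to 10766496 (signal 500). The ligand gene daf-7 had none, and the nearest summits within its 50 kb lay in zip-2 and dos-3. No reproducible summit lay within the 50 kb around the glypican gene lon-2 or the beta-catenin gene bar-1. Support from the replicates was uneven. The sma-9 peak of signal 239 ranked 8520 in replicate 1 and 294 in replicate 2, that of signal 289 ranked 428 and 841, and that of signal 500 ranked 125 and 121. The dbl-1 peak ranked 873 and 3267. Inside daf-16 the strongest peak ranked 385 and 366, and others ranked as low as 2951 in replicate 1 and 4401 in replicate 2. All statements here are about the reproducible list, since the depth that would set a detection limit is unknown.

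The highest peak of the whole list lay inside snpc-4, which encodes a subunit of the complex that starts transcription of small nuclear RNA genes; it was singled out after its value was seen. The peak spanned I 8962814 to 8963494, with its summit in a coding exon, and ranked first in both replicates.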

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

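The tests with GC-matched candidates, without small RNA gene summits, without chd-7, by gene body, and with overlapping intervals counted once, were chosen only after the result was seen. Of 73 recalculations of 10 results, 61 kept their direction and side of the threshold, or for counts stayed within 1.5 times. The 1884 top-ranked pooled candidates are the same peaks as the reproducible list, so that alternative changed nothing and is not counted. Replicate overlap (50.9% to 63.7%), promoter share (26.2% to 52.5%), the excess in the middle of autosomes (odds ratio 1.40 to 1.82) and the number of biotypes past the threshold (4 to 7) held throughout. Lists past the threshold fell from 8 to 4 with the higher-ranked peaks, to 1 with the window of 500 bp up and 100 bp down and to 1 without shared windows, which all leave fewer genes with a summit. With 1 replicate's peaks they were 3 to 4, promoter share was 34.0% to 40.8%, 6-mers 544 to 582, biotypes 6 in each, the X odds ratio 1.2 to 1.29, that of the middle of autosomes 1.40 to 1.5, the promoter difference by signal 7.64 to 7.86 points and peaks near unc-119 0 in each. Peaks near chd-7 were 2 to 9 in these, and 7 in a region of 100 kb (permutation p = 0.0539). The promoter difference by signal was 3.83 points in the higher-ranked peaks and 6.37 with whole intervals. The X odds ratio was 1.04 without small RNA gene summits. 6-mers past the threshold were 179 against GC-matched candidates and 147 with both changes. The ncRNA odds ratio turned to 2.13 with all genes as background and to 1.94 by gene body, and that of protein-coding genes to 1.08 with all genes. The cause was not tested for these. Of 257 recalculated single lists, 36 lost and 4 gained a call. Only the 8 lists that had passed could lose one, so 257 is not the basis for the losses. With 10 alternatives each, these lists kept their call in between 1 (oxidative phosphorylation) and 9 (cytosolic ribosomal proteins and chemoreceptors). Of 288 recalculated named genes, 22 gained or lost their summit, mostly with the narrower window. No paired analysis was possible because there is 1 group. Depth is unknown and sets no limit here that could be computed.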

Other observations

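The comparison of copied with unique tRNA genes, the counts for spliced-leader genes and summit offsets, and the 6-mer tests against GC-matched candidates were chosen only after the result was seen. The spliced-leader SL2 RNA genes, whose RNA is joined to downstream genes of operons, had a reproducible summit within 100 bp in 9 of 18 cases, and sls-2.1 and sls-2.4 were among the 11 highest peaks of the list. None of the 12 annotated SL1 genes had one, and none had any pooled candidate, so no difference between the families was tested. The genes sls-2.1 and sls-2.4 are annotated as snRNA genes, so the snRNA counts above include them. On tRNA genes the summit lay at a median of 19 bp inside the gene from its 5′ end (229 genes), and on snoRNA genes at 32.5 bp upstream of it (70 genes). The quartiles were 21 bp upstream and 53 bp downstream of the 5′ end for tRNA genes, and 54 and 10.25 bp upstream for snoRNA genes. Only summits within 100 bp of the gene were counted, which by itself holds these medians near the gene. Of the 299 tRNA and snoRNA genes with a summit, 143 lay inside a protein-coding gene.

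Of the 179 6-mers that passed against GC-matched candidates, 108 also passed once small RNA gene summits were left out. GTTCGA, part of the internal promoter of tRNA genes, was at 13.0% of summits and 6.63% of GC-matched candidates (adjusted exact p = 4.5e-09), but at 6.93% and 6.61% without those summits (adjusted exact p = 0.901). GAGAGA stood at 32.1% against 13.2% among the other summits (adjusted exact p = 4.9e-32), and the E-box CACGTG at 11.5% against 6.55% (adjusted exact p = 2.4e-05). Of the 1884 summits, 311 lay within 100 bp of a tRNA, snoRNA or snRNA gene, 628 of the rest in a promoter window and 115 of the remainder at an ncRNA gene. A further 324 were intergenic and outside all of these, and 269 were in introns.

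The density of summits at tRNA and snoRNA genes was weighed against technical sources. The values argue against GC content as the whole source: candidates matched for GC lay there in 0.824% of cases, and reproducible summits in 15.3%, a median ratio of 19.3 (central 95% of the draws 12 to 36.1). Of the 140 tRNA genes whose full sequence has no identical copy, 37 had a summit within 100 bp. That was 6.17 times the highest count of 1000 shifts, but it cannot exclude reads shared between copies. Copies that differ by a few bases or share shorter stretches were not counted, and the summit may lie at a copied neighbour. For the 472 genes with an identical copy, shared reads stay open as well. They had a summit 1.54 times as often as genes without one (two-sided Fisher's exact test, p = 0.00207), and shared reads may add to their peaks. Open chromatin at highly transcribed genes was not tested, since neither the control nor expression was analysed here, and no biological explanation was tested because the design has 1 group. The same limit applies to the promoter peaks and the gene lists.

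The peak in snpc-4 had rank 1 in both replicates, so it was not the product of a single library. All 646 words of 36 bases in the peak occur once in the genome (100%), which argues against reads from a repeat. Extra copies of the region stay open: its 50 kb held 18 candidate summits, below the 95th percentile of shifts of 32, but a gain shorter than the region need not raise that count. A binding site and an artefact at this site in all immunoprecipitations were not separated. The lists were already called against a control, which was not analysed here. Whether that control could separate these explanations depends on its kind, which is not described here. No biological explanation was tested.

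The peaks around chd-7 may come from the transgene, which brings extra copies of that gene, and this stays open. The 50 kb held 24 candidate summits, within the 95th percentile of shifts of 31, and another 50 kb tile in the same part of the chromosome held 42. The 50 kb around unc-119 held 7 against a mean of 16.7. How much of either region the transgene carries is not given in the sources used here, and copies shorter than the region need not raise such a count, so not passing the 95th percentile excludes nothing. Candidate counts are not read depth, and no biological explanation was tested.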
